A study of Danio rerio with 2 samples.

How the data were processed

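The data are 2 droplet single-cell RNA libraries, prepared with the Chromium Single Cell 3' kit per the labels' protocols, from hearts of 1 adra1-3i and 1 control group of zebrafish at 7 days after cryoinjury. The values deposited for each library are raw counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization, per the file headers. Counting used Cell Ranger 6.0.1 per the file headers for adra1-3i and Cell Ranger 7.1.0 per the file headers for the control, whereas the submitters' processing notes list 6.0.1 for both; the genome build was GRCz11 per the submitters' processing notes. The annotation release and whether intronic reads were counted are not given in the sources used here. The adra1-3i file holds 8737 barcodes with at least 500 UMIs, so it was filtered before deposit, and the control file holds 2501763 barcodes without a filter. The adra1-3i feature list has 25108 entries including CFP and the control list 25432 without it; mCherry, NTR and GAL4 are in neither. Values were computed over the 25107 identifiers shared by both lists, which carry 24440 symbols, and genes are named by the symbols in those lists. Entries outside the shared set held 0.198% of adra1-3i and 0.0616% of control UMIs.

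Cells were barcodes with at least 1000 UMIs, at least 200 genes and at most 25% mitochondrial counts. Of the control barcodes 59125 held at least 500 but under 1000 UMIs and were left out. Scrublet's automatic threshold marked under 0.5% of over 5000 cells, so it had not worked, and the cells with the highest doublet scores were removed instead, at 0.8% per 1000 cells: 2472 control cells (14.1%) and 366 adra1-3i cells (5.41%). The kept 21502 cells were scaled to 10000 counts, log-transformed, reduced to 30 components of 2000 variable genes, chosen within each library and without haemoglobin, mitochondrial and ribosomal protein genes, joined to 15 neighbours and clustered by Leiden at a resolution of 1, which gave 34 clusters. No integration of the libraries was applied. Cell type markers were fixed before the data were examined. A cluster was named after the class with the most markers among its top 30 genes by fold (prior 20 CPM), with ties settled in the top 10, and needed at least 3. It stayed unnamed if another class had more markers in its top 10, or if its UMI totals were low and none of its markers stood there. That scoring rule was chosen after the data were seen. Clusters 22 (3 macrophage markers, but only a dendritic one in the top 10), 23 and 25 stayed unnamed and held 6.16%, 5.28% and 2.78% of the control's non-erythroid cells and 1.08%, 1.53% and 3.05% of those in adra1-3i. Names are "X-like", since no annotation of cells was used here. Thrombocyte-like cells (119 control and 29 adra1-3i) fell short of the 50 cells required per library and were not compared, which left 9 classes.

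Counts were summed per class and library and given as CPM, counts scaled to a common total of all counts of that sum. The macrophage-like sums held 5988456 UMIs for the control and 13739634 for adra1-3i, and the fibroblast-like sums 1323019 and 5333852. A fold is the ratio of 2 CPM values with an exact conditional Poisson interval at 95%, and a log2 ratio adds 10 CPM to each value. Where a gene has no counts in a library, the fold is a bound from a floor of 3 counts over the class. Shares have exact Clopper-Pearson intervals. With 1 library per group no test was run. The genes to be named were set before the data were examined: per class the highest and lowest log2 ratios among genes with at least 50 CPM and 50 counts in the higher library and a CPM at or above that of the rest of the library, without haemoglobin, mitochondrial and ribosomal protein genes and without clone names (such as those beginning si:, zgc: or BX). This gave 12 and 12 for macrophage-like and fibroblast-like cells and 5 and 5 for the other classes, beside a fixed set (csf1ra, matrix, cytokine, midkine and adrenergic genes) and up to 4 members per list with the largest ratios; 2 genes that these rules pick are not reported here.

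The 23 gene lists were also fixed beforehand: matrix enzymes, collagens, matrix glycoproteins, inflammation, interferon, MHC class II, phagocytosis and lipids, complement, midkine ligands, midkine receptors, growth factors, adrenergic receptors, cell cycle, activated fibroblasts, angiogenesis, lymphatic genes, cardiomyocyte remodelling, glycolysis, immediate early genes, heat shock, Gq signalling, iron and ribosomal proteins. Members needed at least 10 counts in a sum, and a member counted as higher or lower at 1.5-fold. Each median's percentile comes from 10000 random lists of equal size matched in 20 bins of mean expression, and its interval from 200 Poisson redraws. The midkine ligand list had under 3 measured members, so mdka, mdkb and ptn are given singly. Cycling cells were called on cells thinned to 1000 UMIs by at least 2 UMIs of the cell cycle list.

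The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, with seed 0. The interval and list steps were tested on simulated data, with counts drawn for the real genes and 200 genes changed. For macrophage-like sums the intervals held the true fold of 94% of doubled and 95.4% of 7046 unchanged genes, and a list of 50 doubled genes had a median log2 ratio of 0.71, less than 1 because of the prior. For fibroblast-like sums these values were 96%, 94.9% of 2764 and 0.93. With the prior, 76% of doubled but 40% of 2-fold lower genes passed 1.5-fold in macrophage-like sums, against 96% and 74% in fibroblast-like sums, so tallies miss some 2-fold changes. The fold was applied to the adra1-3i side alone, so genes made lower had smaller levels than genes made higher. The gap between them comes with that setting and does not show that tallies miss more lower genes in general. A list of 50 unchanged genes stood at the 82.56th percentile in macrophage-like and the 50.17th in fibroblast-like sums, so percentiles of that order can arise without a difference.

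The 16 alternative settings fixed beforehand cover a minimum of 500 or 2000 UMIs, a mitochondrial maximum of 10%, doublets kept, resolutions of 0.5 and 2, separate clustering of each library, control cells called at 10% of the 99th percentile of UMIs, all cells as the denominator, TMM scaling, totals without haemoglobin, mitochondrial and ribosomal protein genes, subtraction of free RNA, means over cells, thinned cells, a prior of 1 CPM and members with at least 50 counts. Free RNA was estimated from haemoglobin counts, with the profile of control barcodes under 100 UMIs and, for adra1-3i, of all its cells, at 20.6% of control and 5.09% of adra1-3i macrophage-like counts and 32.3% and 9.22% of fibroblast-like counts. A further 3 alternatives were chosen after seeing the data: a free RNA profile from control barcodes of 200 to 800 UMIs, clusters named by the most markers alone, which adds cluster 22 to the macrophage-like class, and a gene's log2 ratio minus its median over at least 3 other classes ("relative to the other classes").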

Results

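Transcripts were counted cell by cell in zebrafish hearts (strain AB/TU) collected 7 days after cryoinjury, dissociated with enzymes and sorted for live cells. The adra1-3i library came from fish carrying UAS:adra1-3i linked to CFP, which GAL4 under csf1ra regulatory sequence, active in macrophages, switches on. The control library carried the same csf1ra driver and the same NTR-mCherry transgene without it. The labels do not say what 3i stands for. Alpha-1 adrenergic receptors are Gq-coupled receptors for noradrenaline and adrenaline, and the study's title names their signalling in macrophages and a programme of extracellular matrix remodelling. Each group held 1 library, so no difference below has a replicate check, and every direction describes these libraries. Intervals are 95% exact intervals and cover counting error only. The files held 71599344 UMIs (counted molecules) for adra1-3i and 166825609 for the control. After filtering, 6397 adra1-3i cells with a median of 7859 UMIs and 15105 control cells with a median of 6495 UMIs entered the comparisons. The control file listed every barcode and the adra1-3i file only barcodes with at least 500 UMIs, so cells were called here at 1000 UMIs in both.

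CFP, the fluorescent reporter carried by the transgene and counted only in the adra1-3i library, was highest in cardiomyocyte-like cells. It reached 15508 CPM (counts scaled to a common total per class) there and was detected in 82.7% (81.0 to 84.3) of those cells at a median of 2352 UMIs. Macrophage-like cells held 251 CPM, with CFP in 56.3% (52.4 to 60.1) of cells at a median of 18991 UMIs. Erythrocyte-like cells, taken as background, held 33.5 CPM in 32.2% of cells at a median of 16158 UMIs. Set against myl7, a cardiomyocyte myosin light chain, CFP gave 20.8 counts (20.1 to 21.6) per 100 myl7 counts in macrophage-like cells, 21.3 in epicardial-like, 20.5 in fibroblast-like, 19.9 in T/NK lymphocyte-like and 17.4 (17.3 to 17.5) in cardiomyocyte-like cells. Endothelial/endocardial-like cells gave 15.1, mural/smooth muscle-like 13.5, erythrocyte-like 11.2 and neutrophil-like 10.8. CFP in macrophage-like cells was thus at the upper end of the range that other classes span and not above it, so CFP made by macrophages was neither shown nor excluded. As a check of the labels, CFP marks the adra1-3i library as carrying the reporter sequence and does not show it in macrophages. The control's feature list has no entry for CFP, so its absence from the control library was not checked.

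**Figure D1:**
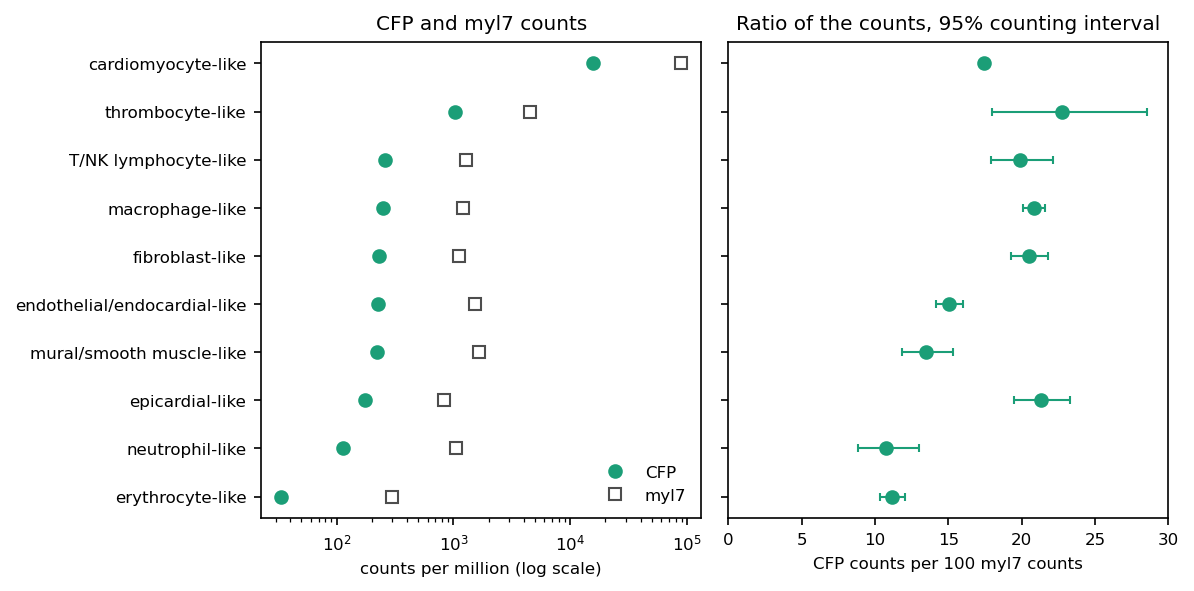
CFP in the adra1-3i library by cell class. The left panel plots CFP and myl7 in CPM on a log scale, and the right panel plots CFP counts per 100 myl7 counts with 95% counting intervals; cardiomyocyte-like cells stand at 15508 CPM and macrophage-like cells at 251 CPM.

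Among non-erythroid cells, macrophage-like cells made up 17.7% (16.6 to 18.9) of the control library and 13.2% (12.3 to 14.2) of the adra1-3i library. Fibroblast-like cells, the main source of scar matrix, made up 4.78% (4.16 to 5.47) of the control and 9.39% (8.60 to 10.2) of adra1-3i. Cardiomyocyte-like cells stood at 25.9% and 42.9%, endothelial/endocardial-like cells at 6.14% and 13.1%, and epicardial-like cells at 5.64% and 4.86%, in the same order. T/NK lymphocyte-like cells were lower in adra1-3i, at 4.11% (3.58 to 4.70) against 19.7% (18.5 to 21.0). Neutrophil-like cells made up 1.59% of the control and 3.11% of adra1-3i, and mural/smooth muscle-like cells 1.40% and 3.05%. Clusters left without a name held 14.2% of the control's and 5.66% of adra1-3i's non-erythroid cells. The live-cell sort, the UMI minimum and the deposit's own filter can all set these shares: erythrocyte-like cells were 72.2% of control cells and 22.1% of adra1-3i cells. With erythrocytes kept in the denominator the macrophage order turned, to 4.94% in the control and 10.3% in adra1-3i. Unnamed cluster 22 had 3 macrophage markers, and counting it as macrophage-like gave 23.9% and 14.3%. With each library clustered by itself the fibroblast shares were close, at 8.79% in the control and 8.67% in adra1-3i.

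**Figure D2:**
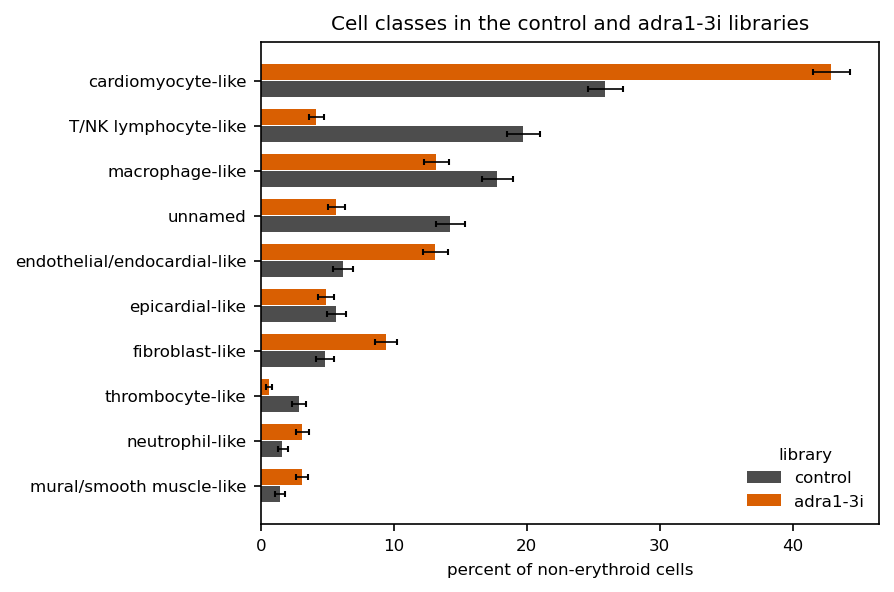
Percent of non-erythroid cells in each class, with bars for the control and adra1-3i libraries and 95% exact binomial intervals. Macrophage-like cells stand at 17.7% and 13.2%, fibroblast-like cells at 4.78% and 9.39%.

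Macrophage-like cells of the adra1-3i library held more RNA for a lipid-binding protein, lectins and fibronectin, mostly in a part of the class described below. They held less RNA for the receptor that sustains macrophages. The fatty-acid-binding protein gene fabp11a stood at 3909 CPM against 35.6 CPM in the control, 109.9-fold higher (96.1 to 126). It is also an endothelial marker, at 4129 CPM in control and 4485 CPM in adra1-3i endothelial/endocardial-like cells, but the other 17 endothelial markers summed to 44.4 and 74.7 CPM in macrophage-like cells. Epicardial markers summed to 1046 and 4872 CPM there, mostly anxa2a and the keratin gene krt8. The jacalin-like lectin genes jac9 and jac2 were 238-fold (142 to 435) and 281-fold (129 to 767) higher. jac3 and jac8 had no control counts and were at least 272-fold and at least 139-fold higher, from a floor of 3 counts over the group; their counts are uncertain, because reads of near-identical copies can be shared. fn1a, which encodes fibronectin, a matrix glycoprotein of the healing heart, was 9.50-fold higher (8.40 to 10.8), at 419 against 44.1 CPM. Also high were the water and glycerol channel gene aqp3a (540.2-fold, 149 to 4463), f13a1a.1 (297-fold, 82.1 to 2457), which encodes the clot-stabilising factor XIII subunit, and ms4a17a.9 (303-fold, 83.8 to 2506). The galectin-related gene lgals9l1 was 9.75-fold higher, the chemokine gene cxcl20 38.9-fold and g0s2, an inhibitor of lipolysis, 31.6-fold. Different clusters held the class in each library: cluster 12 held 93.6% of the control's macrophage-like cells and cluster 13 held 99.1% of adra1-3i's, and jac9 and cxcl8b.1 are among the genes that define cluster 13.

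Most of these high values came from a part of the class. At a clustering resolution of 2, 151 of the 657 adra1-3i macrophage-like cells, with 38.4% of the class's UMIs and a median of 36957 UMIs, formed a separate cluster that had too few macrophage markers to be named and that held 1 control cell. fabp11a reached 9878 CPM in these cells and 182 CPM in the other 506, and jac9 reached 1428 and 11.0 CPM. aqp3a stood at 469 CPM in the separate group and at 0.236 CPM in the rest, and fn1a at 902 and 117 CPM. f13a1a.1 went the other way, at 2.27 CPM in the group and 159.9 CPM in the rest. The macrophage genes csf1ra and mpeg1.1 were lower in the group, at 45.1 and 78.4 CPM, than in the rest, at 107.6 and 189 CPM. Without the group the log2 ratio fell from 6.43 to 2.09 for fabp11a, from 5.52 to 0.77 for jac9, from 4.204 to 0.03 for aqp3a and from 2.99 to 1.24 for fn1a, while f13a1a.1 moved from 3.40 to 4.04 and ms4a17a.9 from 3.43 to 3.55. A cluster almost all from 1 library may be a mark of that library, not a type.

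**Figure D3:**
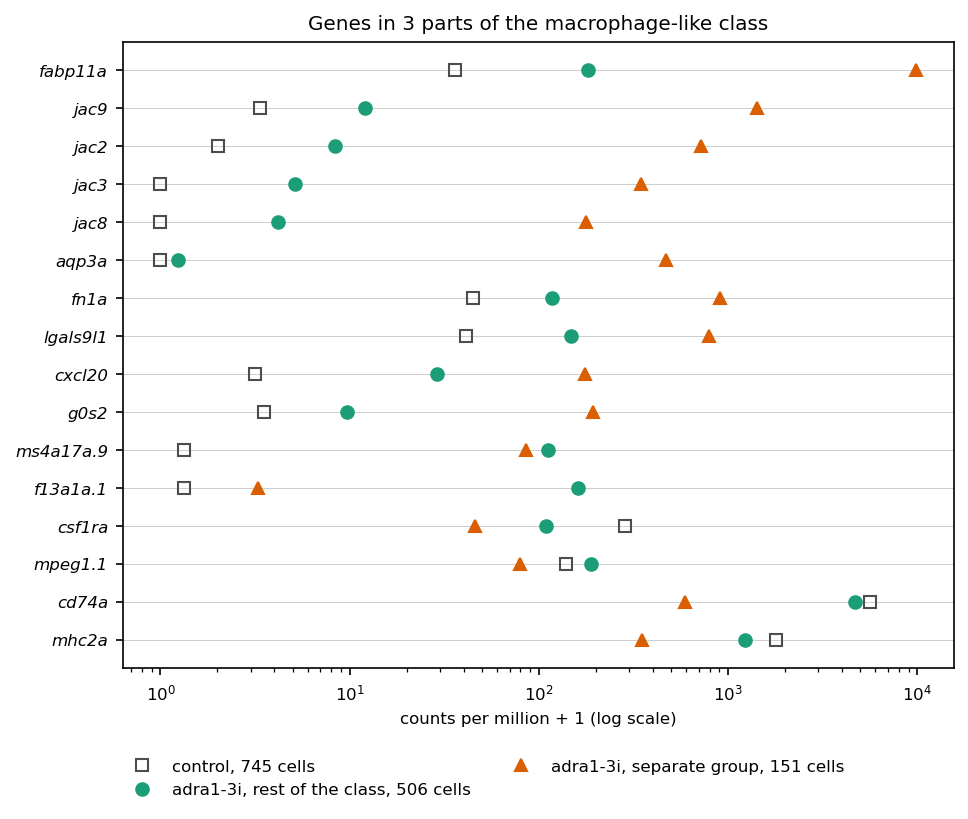
Levels of 16 genes in the macrophage-like class, in CPM plus 1 on a log scale. Squares are control cells, circles the 506 adra1-3i cells that kept the name at a resolution of 2, and triangles the separate group of 151 adra1-3i cells, where fabp11a reached 9878 CPM.

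The lowest genes of adra1-3i macrophage-like cells included herc4, nfkb1 and skila. The ubiquitin ligase gene herc4 stood at 51.5 against 1277 CPM, 24.8-fold lower (23.0 to 26.9). nfkb1, an NF-kB subunit gene, was 33.5-fold lower (27.0 to 41.9), ext1b, a gene of heparan sulfate synthesis, 25.3-fold lower and skila, a co-repressor gene of TGF-beta signalling, 56.3-fold lower. CHST13, erfl3, mindy3, trps1, ago3a, nol4lb, lrmda and pde10a, with folds from 15.3 to 34.01, completed the 12 lowest apart from genes with clone names. All 12 also had a negative median over the other classes, from -0.61 for nol4lb to -3.33 for herc4, so part of each difference was shared. Relative to those classes their log2 ratios ran from -2.91 for nol4lb to -0.79 for pde10a. csf1ra, the receptor for macrophage colony-stimulating factor whose regulatory sequence drives the transgene, was 3.38-fold lower (3.14 to 3.65), at 83.6 against 283 CPM, and its duplicate csf1rb was 2.66-fold lower. No other compared class held more than 1.82 CPM of csf1ra in either library. Whether its difference was shared by all cells could therefore not be checked. The macrophage gene mpeg1.1 differed little, at 146 and 137 CPM (1.07-fold, 0.982 to 1.16).

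**Figure D4:**
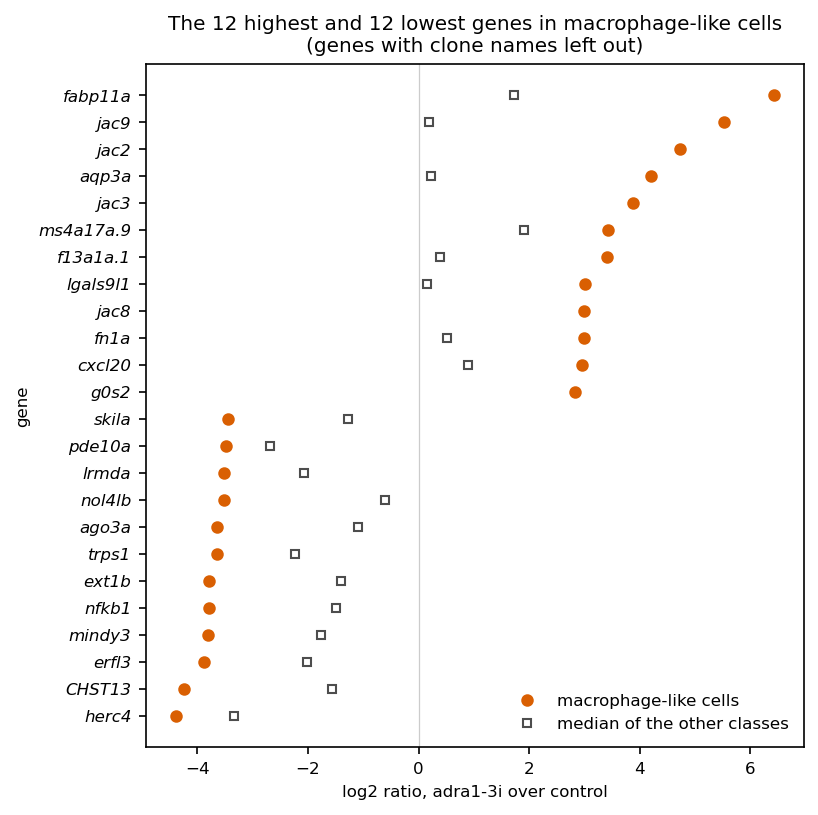
The 12 highest and 12 lowest genes in macrophage-like cells, genes with clone names left out, as log2 ratio of adra1-3i over control. Filled points are macrophage-like cells and open squares the median of the same gene over the other classes, which was negative for all 12 lowest genes and reached -3.33 for herc4.

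Matrix-remodelling genes of macrophage-like cells went both ways. Of 45 measured genes for matrix-remodelling enzymes and inhibitors, 6 were at least 1.5-fold higher and 7 at least 1.5-fold lower, with a median log2 ratio of -0.0021 at the 11.575th percentile of 10000 random lists matched on expression. The lysosomal protease gene ctsd was 2.48-fold higher, while p4ha2, a collagen prolyl hydroxylase gene, was 6.20-fold lower and timp2b, a metalloproteinase inhibitor gene, stood at 523 against 1309 CPM. Outside the separate group timp2b stood at 719 CPM against 1310 CPM in the control. The collagenase genes mmp13a and mmp14b were 1.62-fold and 1.83-fold higher, mmp9 was level at 11.0 CPM in both libraries, and mmp14a was close to undetected at 1.82 and 2.84 CPM. Among 23 matrix glycoprotein genes, 6 were higher and 0 lower (median 0.09, 86.8th percentile): besides fn1a these included tgfbi (2.56-fold, 2.16 to 3.06, and 43.3 CPM outside the separate group against 25.7 CPM in the control), ecm1b (2.89-fold) and sparc (5.11-fold, at 11.9 CPM, log2 0.83, or 0.21 relative to the other classes). That median depended on settings and moved to 0.63 with a prior of 1 CPM and to 0.00 after subtraction of free RNA. Of 18 collagen genes 1 was higher and 0 lower (median 0.11, 97.7th percentile), and the median turned to -0.16 relative to the other classes. Collagen levels were low throughout: col1a2 stood at 7.57 CPM in macrophage-like cells of adra1-3i, against 3890 CPM in its fibroblast-like cells. Of 18 genes of activated fibroblasts, 5 were higher and 2 lower (median 0.42, 99.99th percentile), led after fn1a by anxa2a (5.40-fold) and s100a10b (2.60-fold). Subtraction of free RNA took this median to 0.00, and without the separate group anxa2a stood at 0.07. Outside that group s100a10b stood at 2966 CPM against 2116 CPM in the control.

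Glycolysis and hypoxia genes were the list furthest above its random lists in macrophage-like cells. Of 30 genes, 14 were higher and 3 lower (median 0.54, 100th percentile). The glycolytic enzyme genes gpia, gapdh, eno1a and tpi1b were 3.76-fold (3.41 to 4.15), 3.40-fold, 3.05-fold and 2.84-fold higher. They were higher in most other classes too: relative to these their log2 ratios went from 1.78, 1.64, 1.56 and 1.47 to 0.99, 0.66, 1.02 and 0.83, and the list median to 0.39. gapdh is also among the genes that define cardiomyocyte cluster 6, and cardiomyocyte markers summed to 729 CPM in the control's and 2360 CPM in adra1-3i's macrophage-like cells. gpia and eno1a stood at 289 and 546 CPM in adra1-3i macrophage-like cells and at 60.3 and 158 CPM in the rest of that library. Cell cycle genes followed, with 7 of 37 higher and 0 lower (median 0.30, 100th percentile): the proliferation gene mki67 was 4.34-fold higher (3.00 to 6.51), at 22.5 against 5.18 CPM, and top2a 4.11-fold. The cell cycle median turned to -0.01 with a minimum of 500 UMIs and to -0.19 with each library clustered by itself. In the same order the log2 ratio turned to -0.059 and -0.33 for mki67 and to -0.029 and -0.53 for top2a. Antigen presentation through MHC class II had the lowest median, with 0 of 12 genes higher and 3 lower (median -0.34, 0.210th percentile). mhc2a was 2.01-fold lower (1.96 to 2.07), the invariant chain gene cd74a, which is among the genes that define cluster 12, 1.80-fold lower and the costimulatory gene cd40 3.56-fold lower. Without the separate group this median was -0.04 and cd74a stood at -0.26.

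Inflammatory genes of macrophage-like cells went both ways, with 7 of 33 higher and 9 lower (median -0.11, 1.45th percentile). The neutrophil attractant gene cxcl8b.1 was 7.06-fold higher (6.53 to 7.64), but outside the separate group it stood at 297 CPM against 112 CPM in the control. The NF-kB inhibitor gene tnfaip3 was 9.35-fold lower (log2 -2.86, or -1.53 relative to the other classes, of which all 7 measured had it lower) and csf3a 4.35-fold lower. il1b, a fever-inducing cytokine gene, was 1.75-fold lower (1.65 to 1.85), whereas tnfa was 1.84-fold higher (turned to -0.037 with cluster 22 counted in the class) and tnfb 1.51-fold lower. Outside the separate group il1b stood at 253 CPM against 321 CPM in the control. The inflammatory median turned to 0.04 without the separate group. Interferon response genes had 8 of 27 higher and 1 lower (median 0.15, 88.5th percentile), among them psmb10 at 4.40-fold and gbp1 at 3.48-fold. Heat shock genes had 4 of 28 higher and 10 lower (median -0.24, below every random list). hsph1, a chaperone gene, was 3.59-fold lower while hsp70l was 2.70-fold higher, but relative to the other classes they stood at -0.50 and -0.11 and the list median at -0.079. Iron handling genes had 5 of 19 higher and 7 lower (median -0.29), led by the mitochondrial iron importer gene slc25a37 at 14.6-fold lower; that median turned to 0.13 without the separate group and to 0.054 relative to the other classes. slc25a37 was lower in all 8 other classes too, and erythrocyte markers summed to 122511 CPM in the control's and 11564 CPM in adra1-3i's macrophage-like cells.

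A further 9 lists of macrophage-like cells had medians from -0.10 to 0.29. Phagocytosis, lysosome and lipid genes had 5 of 45 higher and 6 lower (median 0.18), with the integrin gene itgav 5.13-fold lower (log2 -1.93, or -0.97 relative to the other classes) and the cholesterol exporter gene abca1b 3.25-fold lower. Complement and scavenger receptor genes had 3 of 18 higher and 1 lower (median 0.05), with haem oxygenase hmox1a 1.73-fold higher (log2 0.78, or 0.24 relative to the other classes). Growth factor genes had 2 of 25 higher and 2 lower (median 0.08), with pdgfab 5.13-fold higher and hgfb 8.49-fold lower. Angiogenesis genes had 6 of 22 higher and 3 lower (median 0.16, turned to -0.08 after subtraction of free RNA), and the 5 lymphatic genes had 0 higher and 1 lower (median -0.09). Immediate early genes had 6 of 33 higher and 2 lower (median 0.12, turned to -0.09 after the same subtraction), with atf3 2.82-fold higher and nr4a3 2.41-fold lower. atf3 was higher in all 8 other classes too, and its log2 ratio of 1.47 went to 0.13 relative to these. Gq and calcium signalling, the pathway below alpha-1 receptors, had 2 of 27 genes higher and 5 lower (median -0.10, 3.60th percentile), with nfatc2a 10.8-fold and itpr1b 6.66-fold lower. Both were lower in the other classes too, and relative to these their log2 ratios went from -2.33 to -0.76 and from -1.89 to -1.05. Cardiomyocyte remodelling genes had 3 of 16 higher and 1 lower (median 0.29), led by the sarcomere gene tnnt2a at 3.85-fold, a gene of cardiomyocyte RNA. Ribosomal protein genes, a check of scaling, had a median of 0.26 at the 52.5th percentile.

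**Figure D5:**
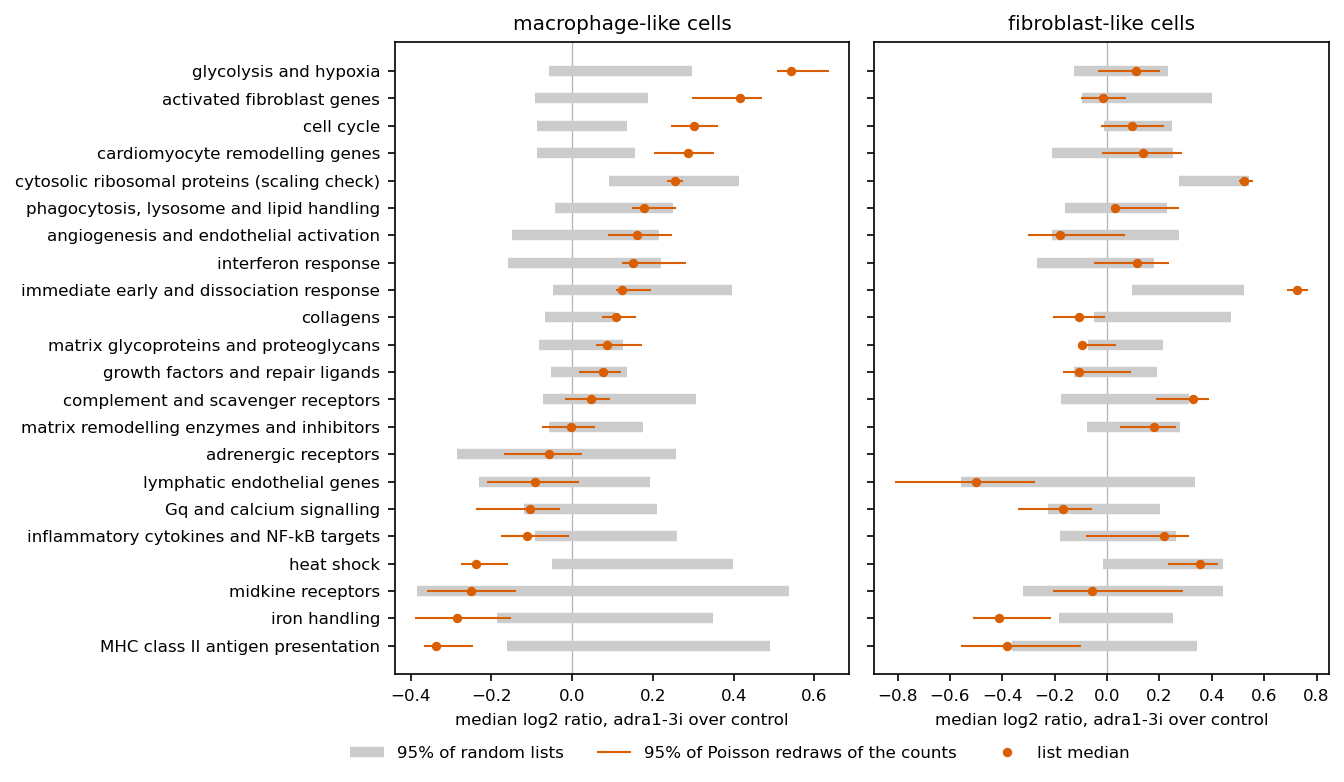
Median log2 ratio of each gene list, adra1-3i over control, in macrophage-like and fibroblast-like cells, each panel on its own scale. Points are list medians, thin lines 95% of Poisson redraws of the counts and grey bars 95% of random lists matched on expression; glycolysis and hypoxia (0.54) and MHC class II (-0.34) are the ends of the macrophage panel.

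Adrenergic receptor genes were counted in few macrophage-like cells apart from adrb2a, a beta-2 receptor gene. The alpha-1 receptor genes adra1aa, adra1ab, adra1ba, adra1bb and adra1d each had 0 or 1 count in the macrophage-like sum of either library. CFP was the only added sequence in the feature lists, so reads of a transgenic receptor had no entry of their own. adrb2a stood at 24.0 CPM in adra1-3i and 20.4 CPM in the control (1.18-fold, 0.955 to 1.46). It was counted in 30.3% and 12.5% of macrophage-like cells at medians of 18991 and 7134.5 UMIs, above the 0.141% and 0.0459% of erythrocyte-like cells at medians of 16158 and 6842.5 UMIs. adra1d was carried by mural/smooth muscle-like cells, at 42.8 CPM in adra1-3i and 60.9 CPM in the control. adrb3a was highest in erythrocyte-like cells, at 11.12 and 48.3 CPM. Of the 4 adrenergic genes measured in macrophage-like cells 0 were higher and 1 was lower (median -0.06).

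Midkine, a heparin-binding growth factor of injured tissue, was expressed mainly by fibroblast-like and epicardial-like cells. mdka stood at 4591 CPM in adra1-3i fibroblast-like cells and 4477 CPM in the control's (1.03-fold, 0.997 to 1.06), and at 2476 and 2087 CPM in epicardial-like cells. In macrophage-like cells mdka stood at 9.10 and 2.84 CPM, against 3.33 and 1.84 CPM in erythrocyte-like cells, and its log2 ratio of 0.57 turned to -0.01 after the added subtraction of free RNA. mdkb was 1.26-fold lower (1.12 to 1.42) in adra1-3i fibroblast-like cells, at 219 against 276 CPM, and turned to 0.54 with each library clustered by itself. ptn, the related pleiotrophin gene, had 2 counts in macrophage-like cells of each library. Of 9 midkine receptor genes in macrophage-like cells 0 were higher and 2 lower (median -0.25, 6.78th percentile): the heparan sulfate proteoglycan gene sdc4 was 1.52-fold lower, at 919 against 1399.9 CPM, and notch2 1.91-fold lower.

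The highest genes of adra1-3i fibroblast-like cells included hsd11b2, dhrs3a and lpl, and the lowest rbms3 and ptgdsb.1. hsd11b2, a glucocorticoid-inactivating enzyme gene, was 6.51-fold higher (5.83 to 7.29), at 1609 against 247 CPM. dhrs3a, a retinaldehyde reductase gene, was 9.98-fold higher (7.14 to 14.4), the lipoprotein lipase gene lpl 17.5-fold higher (8.83 to 40.8) and the MHC class I gene mhc1uba 15.7-fold higher (8.73 to 31.6). The metabolic kinase genes pdk2b and pfkfb4b were 5.82-fold and 7.17-fold higher, and p4hb, a chaperone of collagen folding, 4.79-fold. hist1h4l, ARF5, eif4ebp3l, bzw1b and pdcd4b completed the 12 highest, of which hist1h4l has near-identical copies. ARF5 had a log2 ratio of 2.46 and was nearly as high across the other classes (median 2.12). The RNA-binding protein gene rbms3 was 46.6-fold lower (34.9 to 63.3), and ptgdsb.1, a prostaglandin D synthase gene, 18.5-fold lower (14.2 to 24.3). The BMP receptor gene bmpr1ba had 1 count against 95, a 383-fold difference (67.1 to 15285). zfpm2a, a GATA cofactor gene, creb5b, ptprub, gnb4b, gab2, hdac4, nfixa, aff2 and qkib completed the 12 lowest, with log2 ratios from -3.25 to -2.82, and each had a negative median over the other classes.

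Collagen genes lay low in fibroblast-like cells, with 1 of 23 higher and 7 lower (median -0.11, 1.07th percentile). col12a1b, which encodes a fibril-associated collagen, was 3.54-fold lower (3.03 to 4.14) and its duplicate col12a1a 1.59-fold lower (1.45 to 1.75). The basement membrane gene col18a1a was 3.66-fold lower, col5a3a 2.74-fold and col27a1b 2.64-fold. That collagen median was -0.48 after subtraction of free RNA, 0.08 with trimmed-mean (TMM) scaling and 0.48 with each library clustered by itself. Of 43 matrix-remodelling genes 9 were higher and 6 lower (median 0.18, 78.4th percentile, turned to -0.12 by subtraction of free RNA). loxl2a, a collagen cross-linking enzyme gene, was 3.31-fold higher (2.85 to 3.86), and the membrane protease genes adam8b and adam8a were 4.13-fold and 3.15-fold lower. Matrix glycoprotein genes had 8 of 58 higher and 6 lower (median -0.10, 1.26th percentile, turned to 0.28 with each library clustered by itself): the osteopontin gene spp1, with no control counts, was at least 8.27-fold higher and thbs1b 2.92-fold higher, while vcanb and agrn were 3.59-fold and 2.72-fold lower.

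Fibronectin and periostin genes were near level in fibroblast-like cells. fn1b stood at 3445 CPM in adra1-3i and 3773 CPM in the control (1.095-fold lower, 1.06 to 1.13) and fn1a at 384 and 277 CPM (1.39-fold higher, 1.24 to 1.56). postnb, the periostin gene of activated fibroblasts, stood at 1105 and 1026 CPM (1.08-fold, 1.02 to 1.14), with a log2 ratio of 0.11 that turned to -0.33 after subtraction of free RNA. mmp14b was 1.61-fold higher and mmp14a 1.22-fold higher, and timp2b differed by 1.04-fold (0.905 to 1.18). The activated fibroblast genes together had 6 of 24 higher and 6 lower (median -0.01, 9.09th percentile). Immediate early genes were high, with 19 of 32 higher and 1 lower (median 0.73, 99.99th percentile): cebpd was 3.02-fold, nr4a1 3.08-fold and fosl1a 2.38-fold higher and klf4 5.38-fold lower. Relative to the other classes the immediate early median was 0.02. MHC class II genes had 0 of 9 higher and 3 lower (median -0.38), turned to 0.03 at a resolution of 0.5. Macrophage markers in these cells summed to 351 CPM in the control and 199 CPM in adra1-3i. That sum includes cd74a, which is on the MHC class II list too and stood at 192 and 43.7 CPM. Most of the fall in the sum was that of cd74a, so it is no separate sign of less macrophage RNA.

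Some genes differed the same way in all 9 classes. Across genes, the log2 ratios of any 2 classes correlated with a Pearson r between 0.41 and 0.79 over 36 pairs (median 0.61); genes are not independent replicates. The classes share a library and its free RNA, estimated at 20.6% to 37.6% of the control's counts in the non-erythroid classes, and no value for unrelated classes was available to set these against. herc4 was lower in 9 of 9 classes, with log2 ratios from -4.93 to -2.01. hist1h4l, the ATP synthase gene atp5mea and the ribosomal protein gene rpl26 were higher in 9 of 9, and rpl26 ranged from 1.87 to 4.33.

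Cardiomyocyte-like cells of the adra1-3i library had higher sult2st1 (9.38-fold, 7.43 to 12.01), anxa13l, chac1, sbk3 and atp5mea, the last level with the other classes. They had lower cep85l (114-fold, 67.4 to 209), pdlim5b, a Z-disc gene (12.3-fold), znf1064, the calcium channel gene cacna1g (22.2-fold) and the muscarinic receptor gene chrm2a (16.0-fold). The last pair are among the genes that define cluster 32, which held 5.33% of the control's and 0.748% of adra1-3i's cardiomyocyte-like cells. Remodelling genes of cardiomyocytes had 1 of 20 higher and 4 lower there (median -0.09). Endothelial/endocardial-like cells had higher hist1h4l, spint2 (12.2-fold), the heat shock gene hsp70l (6.25-fold, 6.09 to 6.41), atp5mea and plvapa and lower gab2, rbms3, herc4 and doc2b. Their immediate early genes were high, with 22 of 31 higher and 1 lower (median 0.96, or 0.26 relative to the other classes), and their matrix-remodelling genes low, with 6 of 46 higher and 17 lower (median -0.25), while fibroblast markers in these cells summed to 2202 CPM in the control and 1725 CPM in adra1-3i. Epicardial-like cells had higher hist1h4l, atp5mea, mhc1uba (13.6-fold), rgs2 and ARF5 and lower rbms3, zfpm2a, creb5b, kcnq5a and gria4a (at least 74.6-fold), and of 22 inflammatory genes 2 were higher and 9 lower (median -0.49). rbms3, zfpm2a, creb5b and gab2 were also among the lowest genes of fibroblast-like cells. Across the alternative settings, epicardial-like log2 ratios shrank to as little as -0.56 for rbms3, -0.77 for zfpm2a, -0.76 for creb5b and 0.43 for ARF5. mhc1uba and kcnq5a kept at least 2.29 and -2.09. In endothelial/endocardial-like cells gab2 shrank to -1.30 and hsp70l to 1.17, while spint2 kept at least 2.89.

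T/NK lymphocyte-like cells of the adra1-3i library had higher chemokine genes ccl35.2 (55.0-fold, 27.4 to 129) and ccl34b.9, higher cpa5 and cst14b.2 and higher nkl.1, a killer cell granule gene (7.56-fold), whose log2 ratio of 2.88 turned to -0.01 with a mitochondrial maximum of 10%. The others depended on which cells formed the class: ccl34b.9 and cst14b.2 stood at 0 with 2000 UMIs, the 10% maximum, doublets kept, either other resolution or separate clustering, ccl35.2 at 0.11 with doublets kept and cpa5 at 0.086 with separate clustering. nkl.1 is among the genes that define cluster 21, which held 25.6% of the control's and 53.2% of adra1-3i's cells of this class. cpa5 is among those of the neutrophil cluster, and neutrophil markers summed to 79.1 CPM in the control's and 1266 CPM in adra1-3i's T/NK lymphocyte-like cells. CHST13 (48.4-fold), macrod2, herc4, MAN1C1 and GGT7 (at least 66.3-fold) were lower. Glycolysis genes had 15 of 27 higher and 2 lower in these cells (median 0.64, or 0.20 after subtraction of free RNA), and cardiomyocyte markers there summed to 797 CPM in the control and 2581 CPM in adra1-3i. In neutrophil-like cells the complement gene cfd was 20.6-fold higher (10.8 to 45.3), followed by chka, anxa3b, ip6k2b and tnfb (8.76-fold), while herc4, mindy3, foxo1a, lrmda and dusp19b (at least 59.0-fold) were lower. Inflammatory genes had 10 of 18 higher and 5 lower in neutrophil-like cells (median 0.78, turned to -0.37 with members of at least 50 counts), and heat shock genes 2 of 23 higher and 12 lower (median -0.77). Mural/smooth muscle-like cells, with 59 control cells, had higher c4b (42.7-fold, 11.7 to 353), loxl2a (at least 13.7-fold), ackr3b (at least 11.7-fold), hist1h4l and hsd11b2 and lower erbb4b (111-fold), adcy5, gnb4b, rbms3 and chsy1. ackr3b turned to -0.57 with a mitochondrial maximum of 10%. Collagen genes had 17 of 21 higher and 0 lower in mural/smooth muscle-like cells (median 1.69). Fibroblast markers in this class summed to 7206 CPM in the control and 19110 CPM in adra1-3i, and its own markers to 15991 and 9976 CPM. The fibroblast markers include collagen genes such as col1a2, at 1258 and 4000 CPM, so their sum partly restates the collagen result. Erythrocyte-like cells had higher ptges3a, metap2b, slc20a1a, xiap and the transferrin receptor gene tfr1a (2.80-fold) and lower plagl2 (22.2-fold), thrab, nfixa, dnajb2 and insrb, and 0 of 26 heat shock genes higher and 14 lower (median -0.95). Of the lowest genes named for these classes, CHST13, herc4, mindy3 and lrmda were also among the lowest of macrophage-like cells. rbms3, gnb4b and nfixa were among the lowest of fibroblast-like cells. Their differences were thus not shown to be particular to a class.

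Cycling cells were compared after each cell was thinned to 1000 UMIs and called by at least 2 UMIs of cell cycle genes. Among macrophage-like cells 18.7% (15.8 to 21.9) of adra1-3i and 16.2% (13.6 to 19.1) of the control passed, and among fibroblast-like cells 18.2% and 19.9%. Without thinning the macrophage-like shares were 90.6% and 82.3% and the fibroblast-like shares 85.3% and 79.6%. In cardiomyocyte-like cells 5.32% (4.40 to 6.36) of adra1-3i and 9.64% (7.95 to 11.55) of the control passed, or 24.1% and 39.2% unthinned. T/NK lymphocyte-like cells stood at 26.8% (20.9 to 33.4) and 18.5% (15.9 to 21.3), or 81.5% and 55.5% unthinned. Erythrocyte-like cells, the background, passed at 8.69% (7.28 to 10.3) and 8.51%. The adra1-3i cardiomyocyte-like share was below this background and the control's was near it. The 13 cycling markers summed to 65.6 and 30.2 CPM in cardiomyocyte-like and 34.3 and 26.5 CPM in fibroblast-like cells, against the order of the shares. In macrophage-like and T/NK lymphocyte-like cells they went with the shares. In erythrocyte-like cells they summed to 1.85 and 2.45 CPM, so a background share can arise almost without them. The shares are thus no sure measure of dividing cells. Thinning left out 12 cardiomyocyte-like cells of adra1-3i and, in the control, 1 erythrocyte-like and 1 unnamed cell.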

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

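Of the tests in this part, those of CFP, of the lower and higher genes across the other classes, of the summed jac genes, of the separate macrophage-like group, of doublets and of single genes above every other class were chosen only after the result was seen.

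A pair of signals lay outside the comparisons. CFP stood at 15508 CPM in cardiomyocyte-like cells of the adra1-3i library, a class in which the driver was not named as active. The control file also held 59125 barcodes with at least 500 but under 1000 UMIs that entered no comparison, against 1652 in adra1-3i; haemoglobin made up a median of 66.1% and 8.463% of their counts.

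CFP in cardiomyocyte-like cells was 61.8 times (59.7 to 63.9) its CPM in macrophage-like cells, which argues against RNA leaking out of macrophages. csf1ra stood at 0.0110 times (0.00440 to 0.0227) its macrophage-like CPM there, so a driver that follows the endogenous gene does not explain it either. In macrophage-like cells the 20.8 CFP counts per 100 myl7 counts lay within the 10.8 to 21.3 of the other compared classes, so free cardiomyocyte RNA may account for all CFP counted in macrophages. What stays open is a cardiac promoter carried as a marker on the transgene or activity of the driver in cardiomyocytes; the labels name neither and neither was tested.

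The 307 genes at least 2-fold lower in adra1-3i macrophage-like cells (median log2 ratio -1.70) were mostly lower elsewhere as well. Of 273 measured in erythrocyte-like cells 88.3% were lower there, against 52.3% of all 9410 genes measured in both classes. That share takes any negative ratio, also of genes near the floor. csf1ra counted as lower at 0.512 CPM in the control against 0.0900 CPM in adra1-3i, and mhc2a at 2.11 against 1.13 CPM. For such genes it cannot tell whether the difference was shared. The median over the other classes was -0.92 for 277 genes. For the set as a whole, but not for each gene, this argues against an effect limited to csf1ra-expressing cells. Free RNA of the control was not the main source for most of these genes. Of them, 4.23% (2.27 to 7.13) were higher in its near-empty barcodes than in its macrophage-like cells, and for those free RNA stays open. A smaller contribution to the others was not measured by this test. The set includes erythrocyte markers such as hemgn and alas2. Erythrocyte markers in macrophage-like cells summed to 122511 CPM in the control and 11564 CPM in adra1-3i. A difference of library or read counting shared by all cells may explain part of this pattern. Cell Ranger 7.1.0 in the control against 6.0.1 is a candidate source. It was not tested, since neither the reads nor an annotation of introns was at hand. With 1 library per group an effect of the transgene on other classes through macrophages stays open too.

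Of the 49 genes at least 4-fold higher in adra1-3i macrophage-like cells, 22 were at 50 CPM or more in at least 3 other classes. Of these, 8, among them fabp11a, fn1a and krt94, had a ratio more than 2-fold that of every such class beyond counting error. For these 8 that argues against a shift shared by all cells. Of the 22, 50% (28.2 to 71.8) lay more than 2-fold above the median of the others. For the rest of the 22 as a set a shared shift thus stays undecided. Among them hist1h4l and atp5mea were higher in all 9 classes, so a shared shift may explain both, at least in part. The other 27 genes could not be tested. The summed 8 jac genes had a log2 ratio of 6.17 (14520 counts against 29), which argues against reads split differently among copies. RNA from another named class does not explain the 23 genes, such as jac9 and cd9b, that were above every such class of adra1-3i beyond counting error, but 51.0% (36.3 to 65.6) of the 49 were higher in another class and for the remaining genes it stays open. For 36.7% (23.4 to 51.7) of them the log2 ratio was below 0.5 times its value without the separate group of 151 cells, which may account for part of the pattern; 53.1% (38.3 to 67.5) were higher in that group than in every other class and 24 lay beyond counting error above those classes and the rest of the class, which argues against doublets with a named class for these 24 and leaves them open for the others. An effect of the transgene on macrophages is the biological explanation the design gives, and with 1 library per group it cannot be separated from other differences between the fish or the preparations.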

How the results depend on the processing

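The ratios relative to the other classes, the free RNA profile from barcodes of 200 to 800 UMIs and the counting of cluster 22 as macrophage-like were chosen only after the results were seen, and the other alternatives were planned. Of 3316 alternative log2 ratios of 198 named genes, 3238 kept their direction, 2001 stayed within the main interval and 34 turned beyond it. Of 657 alternative medians of 37 lists, 601 kept their direction and 27 turned beyond the main interval. The others changed sign where that interval covered both signs, or fell to no difference. Of 175 alternative class shares 99 stayed within the main interval, as did 11 of 18 CFP ratios. Values below are log2 ratios or percent of non-erythroid cells, control before adra1-3i, and the cause was not tested for any of them.

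Shares moved with the choice of cells. With 500 UMIs the fibroblast-like share was 5.82% in the control and the macrophage-like share 10.9% in adra1-3i. With 2000 UMIs the macrophage-like shares were 19.9% and 16.2% and the adra1-3i fibroblast-like share 10.7%. A 10% mitochondrial maximum gave 15.9% macrophage-like control cells and 11.4% fibroblast-like adra1-3i cells. With doublets kept, fibroblast-like shares were 5.82% and 11.3% and the control's macrophage-like share 16.4%. Resolution 0.5 gave fibroblast-like shares of 11.599% and 17.3%, and resolution 2 gave 3.92% and 7.84%, with 10.2% macrophage-like adra1-3i cells. Separate clustering gave 8.79% fibroblast-like control cells and macrophage-like shares of 15.7% and 10.3%. The order-of-magnitude rule gave fibroblast-like shares of 6.94% and 10.8% and 21.6% macrophage-like control cells. With cluster 22 counted as macrophage-like the macrophage-like shares were 23.9% and 14.3%. Of all cells, fibroblast-like shares were 1.33% and 7.32% and macrophage-like shares 4.94% and 10.3%.

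In fibroblast-like cells the matrix enzyme median turned to -0.051 with 2000 UMIs, to -0.052 with doublets kept and to -0.12 and -0.14 with the planned and added subtraction of free RNA. The collagen median was -0.24 with 2000 UMIs, 0.0058 with a 10% mitochondrial maximum, 0.00082 with doublets kept, -0.23 at resolution 2, 0.48 with separate clustering, 0.075 with TMM scaling, -0.23 with totals without haemoglobin, mitochondrial and ribosomal genes, -0.48 and -0.42 with the planned and added subtraction and -0.49 relative to the other classes. The matrix glycoprotein median was 0.11 at resolution 0.5, -0.17 at resolution 2, 0.28 with separate clustering, 0.042 with TMM scaling, -0.18 with the reduced totals, -0.36 and -0.35 with the subtractions, -0.14 with a prior of 1 CPM and -0.17 relative to the other classes. The MHC class II median turned to 0.026 at resolution 0.5.

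In macrophage-like cells the matrix enzyme median was -0.17 and -0.20 with the subtractions and 0.071 with members of at least 50 counts. The collagen median turned to -0.16 relative to the other classes and to -0.048 with the added subtraction. The matrix glycoprotein median was 0.21 with 500 UMIs, 0.026 with the order-of-magnitude rule, 0.00 and -0.10 with the subtractions, 0.66 with thinned cells, 0.63 with a prior of 1 CPM, 0.76 with members of at least 50 counts and 0.047 with cluster 22 counted in the class. That last setting also turned growth factors to -0.0013 and tnfa to -0.037. With the planned and added subtraction the angiogenesis median turned to -0.081 and -0.15 and the immediate early median to -0.086 and -0.077. With the added one alone, growth factors turned to -0.0092 and activated fibroblast genes to -0.0067. Cell cycle genes turned to -0.0070 with 500 UMIs and to -0.19 with separate clustering. Resolution 2, which takes the separate group of 151 cells out of the class, turned inflammatory genes to 0.036 and iron handling to 0.13. Relative to the other classes immediate early genes turned to -0.50, iron handling to 0.054 and ribosomal proteins to -0.26. In neutrophil-like cells the inflammatory median turned to -0.37 with members of at least 50 counts.

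Single genes turned as follows. In fibroblast-like cells postnb stood at -0.23 with 500 UMIs, -0.054 with 2000 UMIs, -0.26 with doublets kept, -0.11 at resolution 2, -0.069 with the order-of-magnitude rule, -0.010 with the reduced totals, -0.33 and -0.26 with the subtractions and -0.37 relative to the other classes. mdkb stood at 0.037 with doublets kept, 0.38 at resolution 0.5 and 0.54 with separate clustering, and mmp14a at -0.039 with 2000 UMIs and at -0.15 and -0.074 with the subtractions. fn1b stood at 0.063 with separate clustering, 0.058 with TMM scaling and 0.0018 as a mean over cells. Relative to the other classes fn1a (-0.18) turned in fibroblast-like cells, atp5mea (-0.083) in cardiomyocyte-like cells and hsp70l (-0.11) and dnajb1a (0.11) in macrophage-like cells. In macrophage-like cells mki67 and top2a stood at -0.059 and -0.029 with 500 UMIs, and separate clustering gave -0.33 for mki67, -0.22 for stmn1a, -0.53 for top2a and -0.13 for rrm2. At resolution 2 lpl stood at -0.22 and aldh1a2 at -0.17, and with the added subtraction mdka at -0.014. A 10% mitochondrial maximum turned nkl.1 in T/NK lymphocyte-like cells to -0.0088 and ackr3b in mural/smooth muscle-like cells to -0.57.

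TMM scaling multiplied the adra1-3i total of a class by a factor, so log2 ratios moved by up to its log2 with the sign turned. The log2 factor was -0.19 in fibroblast-like, -0.28 in mural/smooth muscle-like, -0.20 in endothelial/endocardial-like, -0.13 in neutrophil-like, 0.30 in T/NK lymphocyte-like and 0.14 in erythrocyte-like cells, and under 0.1 in size in the others. Depth limits the smaller classes most, such as the 59 control mural/smooth muscle-like cells. Of the 198 genes, separate clustering gave values for 188, resolution 0.5 for 178 and the ratio relative to the other classes for 178, and of the 37 lists for 36, 35 and 36; thinned cells gave 34 list medians and members of at least 50 counts gave 35. Of the 18 class shares, separate clustering gave 17 and resolution 0.5 gave 14. No paired analysis was possible because each group has 1 library.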

Other observations

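The values in this part were picked after the data were seen. The separate group of 151 macrophage-like adra1-3i cells had a profile of its own beyond the genes named above. The membrane-binding gene anxa2a stood at 5953 CPM in it and at 496 CPM in the other 506 cells of the class, and its partner gene s100a10b at 9593 and 2966 CPM. cdh1, which encodes the adhesion protein E-cadherin, stood at 153 CPM in the group and at 1.18 CPM in the rest. The chemokine gene cxcl8b.1 stood at 1618 and 297 CPM. The antigen presentation genes cd74a and mhc2a were lower in the group, at 593 against 4707 CPM and 350.3 against 1234 CPM, and so was il1b, at 73.5 against 253 CPM. The myeloid genes spi1b and marco were present in both, at 307 and 547 CPM in the group and 404 and 719.7 CPM in the rest.

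The clusters left unnamed were led by immune genes in part. Cluster 25, with 117 control and 152 adra1-3i cells, was led by the immunoglobulin genes igic1s1 and ighv1-4. Cluster 22, with 259 control and 54 adra1-3i cells, was led by genes including the chemokine gene ccl35.1 and mhc2a, and cluster 23, with 222 and 76 cells, by genes including star, hist1h4l and stmn1a.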
